A study of Homo sapiens with 4 samples.

How the data were processed

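RNA from 4 MCF-7 libraries, 2 WT and 2 RSK2KO, was sequenced as paired reads. Libraries were made with a TruSeq kit and run on an Illumina HiSeq 2500, per the labels' protocols and the series' design text. Reads were aligned to hg38 (GRCh38) and compared in CLC Workbench 10.0 by the authors, per the same text. The annotation release, mapping settings, treatment of reads that map to several places and use of strand are not given in the sources used here.

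The deposited table held 42328 genes with 4 kinds of value per library. The total counts are raw reads per gene as the authors deposited them, and they alone entered the gene tests. The RPKM values, per the file headers, are reads scaled by gene length and by mapped reads. The TPM values, per the file headers, are the same values rescaled so that each library has a common sum. The column headed CPM in the deposited table is a signal of counts scaled by an effective library size rather than by the plain total. The table also held the authors' deposited fold changes, p-values and FDR values. A count above 0 was listed for 16393 genes, of which 99.0% are protein coding in GENCODE release 44, where 41900 of the table's genes were matched and 428 were not. A further 5095 genes had an RPKM above 0 with a count listed at 0, and 4911 of them are not protein coding. Those genes were left out of the count tests and examined separately. Coordinates are those of the deposited table.

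Total counts ranged from 31265887 to 40215345 per library. Replicates differed by more than sampling noise (chi-square per degree of freedom 24.1 for WT and 25.2 for RSK2KO), so none was a duplicate deposit. Groups came from the sample titles. No value column of the table was left unmapped.

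Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (13121 genes), scaled by TMM and tested with edgeR's quasi-likelihood test for RSK2KO against WT, with no covariate. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes are the fold change over the square root of the F statistic. CPM values are TMM-scaled. With 2 libraries against 2, no permutation test of the groups can reach 0.05, since chance alone separates the groups in 33.3% of cases, and no count of other splits was made.

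The genes named were fixed by a rule before the data were examined, as were the 23 gene lists, the tests and the alternatives below, except where stated. The rule took RPS6KA3 first. It then took the 12 largest rises and the 12 largest falls among called genes with at least 5 CPM in the higher group, no overlap between the groups and an approved-style symbol without a clone name or locus number. From each list it took up to 4 called members with the smallest adjusted p, or the 2 most highly expressed where none was called. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. They cover the RSK family, estrogen-induced, luminal, basal and mesenchymal, G1/S, G2/M, MAPK, ERBB, stress-response, ribosomal protein, ribosome biogenesis, cholesterol, glycolysis and hypoxia, interferon, NF-kB, p53, apoptosis, adhesion, CREB, fibroblast, immune and endothelial, mitochondrially encoded and histone genes.

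The alternatives were DESeq2's size factors, scaling by total count only, no filter on low counts, the replicate number as a block, each library left out in turn, the Wald test of DESeq2 1.42.0, limma-voom, edgeR's glmTreat against a fold change of 1.5, an adjusted p under 0.01, camera with an estimated correlation, and limma's fry for a change in 1 direction. Camera with an estimated correlation rests on the few residual degrees of freedom of 2 libraries per group, which limits what it can detect. With a library left out, the lone library of its group is assumed to vary like the other group. Leaving out the genes of shifted chromosome segments, and comparing with the authors' deposited comparison, were added after seeing the data. An alternative with another count column was not run, because the table has 1 count column. Alternatives for normalized values did not apply.

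For positions, log2 fold changes less their median were ordered along each chromosome, and running medians over 51 genes were compared with the largest in 1000 random gene orders. Windows of 31 and 101 genes were also tried, chosen after seeing the data. The 95% intervals of medians are bootstrap intervals, from 2000 draws for segments and 10000 for the neighbours of RPS6KA3. Genes with a count listed at 0 and an RPKM of at least 0.5 in at least 2 libraries were tested with limma (trend) on log2(RPKM + 0.1), a scale that understates the change of low genes. Groups of at least 8 tested genes with a shared symbol root were tested with Fisher's exact test, one-sided. Very short roots, open reading frame and locus names, and the roots FAM, KIAA, ZNF, TMEM, CCDC and ANKRD were left out.

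The steps were tested on simulated data. Counts for the 13121 genes were drawn with 200 genes changed. With dispersions per gene, the test recovered 44% of genes changed 1.5-fold, 76% at 2-fold, 100% at 4-fold and 98% at 8-fold, and 15.4% of 188 calls were false. With dispersions on the trend, it recovered 48%, 78%, 96% and 100%, and 3% of 166 calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.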

Results

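Gene expression was measured by RNA sequencing in MCF-7 cells, an estrogen receptor-positive human breast cancer line, of 2 genotypes. The wild-type group (WT) and the group in which RSK2 was knocked out (RSK2KO) held 2 libraries each. RSK2 is a serine/threonine kinase that acts downstream of ERK and is encoded by RPS6KA3. All 4 libraries came from cells kept without serum for 12 to 15 h and then given 10 nM epidermal growth factor (EGF) and 1 nM estradiol (E2) for 8 h. The design therefore compares the genotypes within 1 stimulated state, and no library of unstimulated cells was analysed here. The total count was 40215345 in WT replicate 1, 35230856 in WT replicate 2, 31265887 in RSK2KO replicate 1 and 38794109 in RSK2KO replicate 2. Log2 CPM, the count of a gene scaled by the size of its library, correlated across genes at 0.991 within each group and at 0.967 to 0.975 between groups, where genes are not independent replicates. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Nor do they say whether the RSK2KO cells were a single clone or a pool. Differences between the groups therefore cannot be told apart from other differences between the 2 cell populations.

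The targeted transcript, RPS6KA3 (GRCh38, chromosome X, 20149911 to 20267100, minus strand), was lower in both RSK2KO libraries than in both WT libraries. Its raw counts were 6181 and 6312 in the WT libraries and 3930 and 4834 in the RSK2KO libraries. Its level was 168 ± 18.6 CPM in WT and 124 ± 3.48 CPM in RSK2KO (SD, n = 2 each), a log2 fold change of -0.44 with a standard error (SE) of 0.099 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0257). The transcript therefore stood at 0.737 of its WT level. The call was lost without RSK2KO replicate 1 and without RSK2KO replicate 2, where the log2 fold change stayed at -0.46 and -0.41. Among the 6 tested members of the RSK and MSK kinase family, 2 rose, 1 fell and 3 did not pass the test, and the counts adjusted over the list alone were the same. RPS6KA6, which encodes RSK4, rose 2.23-fold from 10.7 ± 0.296 CPM in WT (SD, n = 2, edgeR adjusted p = 0.0117). RPS6KA2, which encodes RSK3, rose by a log2 fold change of 0.58 (edgeR adjusted p = 0.0441), a call that was lost without WT replicate 1 (edgeR adjusted p = 0.117), RSK2KO replicate 1 (0.106) or RSK2KO replicate 2 (0.155). RPS6KA1, which encodes RSK1 and was chosen after its values were seen, stood at 34.6 ± 0.273 CPM in WT and 35.1 ± 0.638 CPM in RSK2KO (edgeR adjusted p = 0.907). As a set the family did not pass the list test (camera adjusted p = 0.561).

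Of 13121 genes tested, 1029 were higher and 1232 were lower in RSK2KO. These were 17.2% of the genes tested, and 347 of the higher and 424 of the lower genes differed by at least 2-fold. Of all genes tested, 62.9% had both libraries of one group above both of the other, which chance alone gives for 33.3% of genes. The counts were lower without RSK2KO replicate 1, at 503 higher and 576 lower, and without RSK2KO replicate 2, at 605 and 711.

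The largest rises among the genes named by the fixed rule included a receptor, epithelial differentiation genes and a steroid-conjugating enzyme. MC4R, a melanocortin receptor, rose 91.9-fold from 0.294 ± 0.00964 to 27.5 ± 17.0 CPM (SD, n = 2 each, edgeR adjusted p = 0.00137). MUCL1, which encodes a small mucin of breast epithelium, rose 26.9-fold from 0.658 ± 0.0443 to 17.8 ± 3.36 CPM (edgeR adjusted p = 0.000267). SPRR1B and SPRR3, small proline-rich proteins of the cornified envelope, rose 13.7-fold and 12.1-fold, and ABCA12, a lipid transporter of the epidermis, rose 10.0-fold from 3.04 ± 0.178 to 30.4 ± 3.50 CPM. GPNMB rose 33.1-fold, but its RSK2KO libraries were far apart at 16.8 ± 14.5 CPM. UGT2B15, which glucuronidates steroids, rose 17.9-fold. GUCY1A3, a subunit of soluble guanylate cyclase, rose 32.9-fold, and GNA14, a G protein subunit, rose 9.37-fold. KLHL4, FAM83E and FAM84A rose by log2 fold changes of 3.55, 3.52 and 3.46. Leaving out 1 library moved the log2 fold change of MC4R from 6.52 to 5.71 (without RSK2KO replicate 1) and that of GUCY1A3 from 5.04 to 4.45 (without RSK2KO replicate 2). That of UGT2B15 moved from 4.16 to 4.82 without WT replicate 2 and to 3.54 without RSK2KO replicate 2. That of GPNMB moved from 5.05 to 3.69 without RSK2KO replicate 1, to 5.75 without RSK2KO replicate 2 and to 5.90 without WT replicate 2, and its call was lost in limma-voom (adjusted p = 0.0539). UGT2B15 and the SPRR genes have close paralogs, and how reads shared between copies were counted is not given in the sources used here, so their values are uncertain. MC4R lies in a segment of chromosome 18 whose genes were higher as a whole, by a median log2 fold change of 0.43.

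The largest falls included genes of the extracellular matrix, cell adhesion and hormone or prostaglandin metabolism. FBN2, a fibrillin, was 16.3-fold lower at 0.971 ± 0.191 CPM against 16.0 ± 11.3 CPM in WT (SD, n = 2 each, edgeR adjusted p = 0.00486). FAT1, an atypical cadherin, was 14.8-fold lower, from 92.5 ± 20.6 to 6.16 ± 2.62 CPM (edgeR adjusted p = 0.000731). DIO2, the deiodinase that activates thyroid hormone, was 14.1-fold lower, and PTGES, which makes prostaglandin E2, was 9.34-fold lower. FHL2, a LIM-domain cofactor, was 7.20-fold lower, from 249.7 ± 46.5 to 34.7 ± 1.85 CPM (edgeR adjusted p = 0.000267). SNAI2, the transcriptional repressor Slug, was 7.83-fold lower, and BAMBI, a decoy receptor of the TGF-beta family, was 7.61-fold lower. BCL2A1, an anti-apoptotic member of the BCL2 family, was 12.9-fold lower. ZNF827, TDRD1, PSCA and SPOCD1 were 9.28-fold, 8.32-fold, 8.10-fold and 7.93-fold lower. Without WT replicate 1 the log2 fold change moved from -4.03 to -3.02 for FBN2 and from -3.02 to -2.07 for PSCA. Without RSK2KO replicate 2 that of BAMBI moved from -2.93 to -3.79. BAMBI lies in a segment of chromosome 10 whose genes were lower as a whole, by a median log2 fold change of -0.37.

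**Figure D1:**
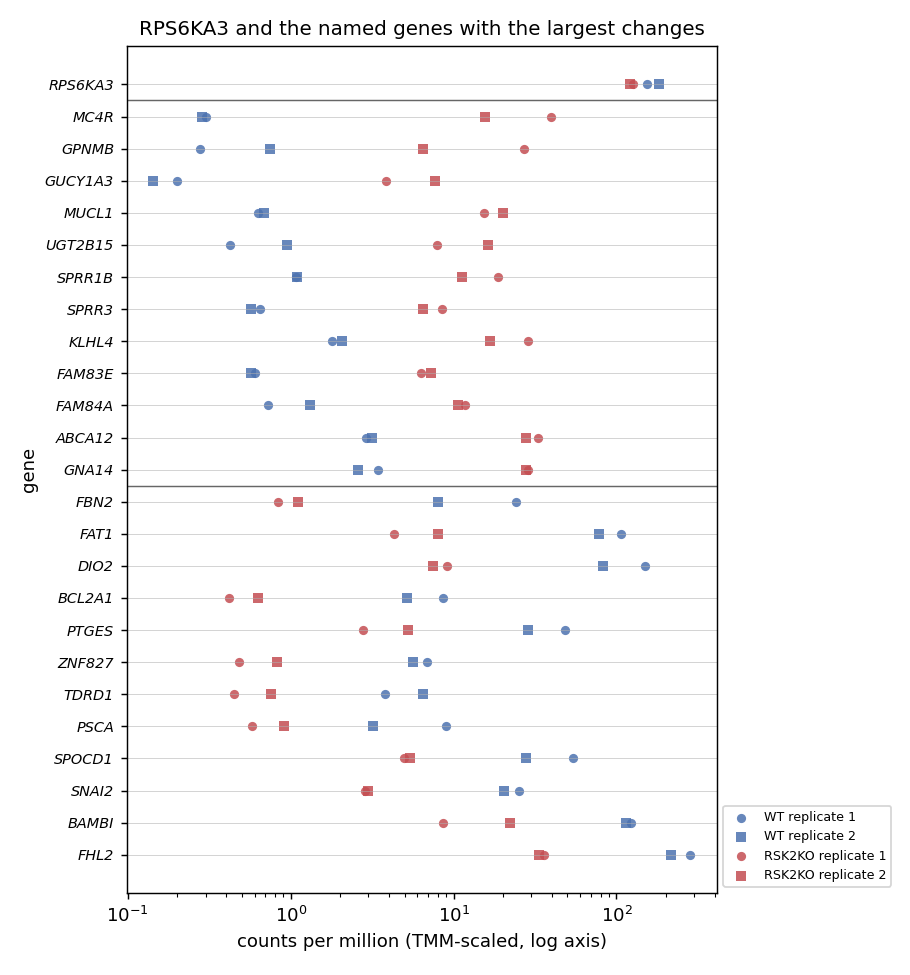
Each point is the TMM-scaled CPM of 1 library on a log axis, for RPS6KA3 (top), the 12 named genes with the largest rises (middle) and the 12 with the largest falls (bottom), with WT in blue, RSK2KO in red, replicate 1 as circles and replicate 2 as squares. In each gene the WT and RSK2KO libraries do not overlap, which the rule required of the largest rises and falls. The gap for RPS6KA3 is small, from 168 to 124 CPM.

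The list of estrogen-induced genes, the one closest to the study's question, moved in both directions. Of its 46 tested members, 7 rose, 12 fell and 27 did not pass the test, and 12 rose and 17 fell when adjusted over the list alone. SLC39A6, a zinc transporter, rose 3.20-fold from 419 ± 80.3 to 1342 ± 98.2 CPM (SD, n = 2 each, edgeR adjusted p = 0.00116). SLC7A5, a transporter of large neutral amino acids, was 3.02-fold lower (edgeR adjusted p = 0.00053), and WISP2 was 3.81-fold lower (edgeR adjusted p = 0.000731). Some canonical members were chosen after their values were seen. TFF1 was 1.34-fold lower (edgeR adjusted p = 0.0318), whereas PGR, the progesterone receptor, had a log2 fold change of 0.93 (edgeR adjusted p = 0.0611) and GREB1 one of 0.60 (edgeR adjusted p = 0.108), neither past the threshold. The list had a median log2 fold change of -0.10 and did not pass the list test (camera adjusted p = 0.176). Without WT replicate 1 it passed in the lower direction (camera adjusted p = 0.000269), and without WT replicate 2 its direction turned (camera adjusted p = 0.797). The number lower was 19 without WT replicate 1, and the number higher was 15 without WT replicate 2. Of the called members, SLC39A6, BCL2, RET and CA12 lie in chromosome segments that were shifted as a whole. RET and CA12 were chosen after their values were seen. SLC39A6 and BCL2 both lie in the raised segment of chromosome 18, where SLC39A6 rose and BCL2 fell.

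Genes of luminal identity rose as a set by the list test with a preset correlation. Of 24 tested, 4 rose and 3 fell, 7 rose and 3 fell when adjusted over the list alone, and the median log2 fold change was 0.21 (camera adjusted p = 0.045). The adjusted p was 0.806 with an estimated correlation and 0.0607 without WT replicate 1. The number higher was 10 without WT replicate 2, and the number lower was 1 without RSK2KO replicate 1. SPDEF, an epithelial transcription factor, rose 2.29-fold from 52.6 ± 3.02 to 120.1 ± 6.02 CPM (SD, n = 2 each, edgeR adjusted p = 0.00079). AGR2, a disulfide isomerase, rose 2.24-fold (edgeR adjusted p = 0.00161), and TBX3, a T-box repressor, was 1.76-fold lower (edgeR adjusted p = 0.00373). Basal and mesenchymal genes went both ways, with 3 higher and 5 lower of 21 (6 and 6 adjusted over the list alone, camera adjusted p = 0.327). The basal keratin KRT17 was 6.51-fold lower and KRT6A was 2.18-fold higher, both with close keratin paralogs that make the values uncertain. ANXA1, an annexin, rose 7.26-fold from 6.84 ± 0.498 to 49.8 ± 17.8 CPM (edgeR adjusted p = 0.00126). Without RSK2KO replicate 1 the basal list passed in the lower direction (camera adjusted p = 0.00985), and without RSK2KO replicate 2 its direction turned (0.566). The number lower was 8 in the first case, the number higher was 7 in the second, and 5 were higher without WT replicate 1.

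Genes induced by MAPK signalling, together with its feedback regulators, were lower as a set. Of 41 tested, 8 fell and 1 rose, 9 fell and 1 rose when adjusted over the list alone, and the median log2 fold change was -0.21 (camera adjusted p = 0.00748, and adjusted p = 0.806 with an estimated correlation). Without WT replicate 2, 4 rose. FOSL1 and FOSL2, AP-1 transcription factors, were 3.01-fold and 2.18-fold lower, from 53.7 ± 6.30 to 17.8 ± 4.08 CPM and from 313 ± 6.58 to 144 ± 12.4 CPM (SD, n = 2 each, edgeR adjusted p = 0.00204 and 0.00103). EPHA2, an ephrin receptor, was 1.98-fold lower, and DUSP7, a phosphatase of ERK, was 1.77-fold lower within a lowered segment of chromosome 3. Among 20 receptors, ligands and regulators of the ERBB family, 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.48), and 4 fell without WT replicate 1 and 2 without WT replicate 2 or RSK2KO replicate 1. ERBB4 rose 2.89-fold from 47.3 ± 0.523 to 136 ± 15.9 CPM (edgeR adjusted p = 0.000731), and the ligand BTC was 2.88-fold lower (edgeR adjusted p = 0.00639). Of 16 targets of CREB, 2 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.48), with 4 higher and 1 lower without WT replicate 1, 4 higher without WT replicate 2 and 1 higher without RSK2KO replicate 1. They were NR4A2, an orphan nuclear receptor (2.14-fold, edgeR adjusted p = 0.0169, and 0.0628 without RSK2KO replicate 2), and VGF, a secreted neuropeptide precursor (1.40-fold, edgeR adjusted p = 0.0348, and 0.169 without RSK2KO replicate 1). Of 15 targets of NF-kB, 3 fell (2 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0682), among them TNFAIP2, 3.59-fold lower (edgeR adjusted p = 0.00545). This list passed in the lower direction without RSK2KO replicate 2 (camera adjusted p = 0.0298), with no filter on low counts (0.0475) and without the genes of the shifted chromosome segments (0.0466). Its calls were 1 lower without RSK2KO replicate 1, and 1 higher and 4 lower without WT replicate 2.

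Ribosome biogenesis genes were lower as a set, with the smallest p of the 23 lists by camera at the preset correlation over all 4 libraries. The rank did not hold with an estimated correlation. Of 30 tested, 12 fell and none rose, 17 fell when adjusted over the list alone, and all 30 had a fold change below 0, with a median log2 fold change of -0.28 (camera adjusted p = 6.63e-05, and adjusted p = 0.806 with an estimated correlation). The number lower was 2 without RSK2KO replicate 1, 2 without RSK2KO replicate 2 and 8 without WT replicate 1, each at 0 higher, while the camera adjusted p stayed at 0.00444 or below. BOP1, a factor of large-subunit assembly, was 1.61-fold lower, from 178 ± 8.49 to 111 ± 0.101 CPM (SD, n = 2 each, edgeR adjusted p = 0.00301). RRP9, a component of the U3 snoRNP in a lowered segment of chromosome 3, was 1.71-fold lower (edgeR adjusted p = 0.00819). Of 76 cytosolic ribosomal protein genes, 4 fell and none rose (3 adjusted over the list alone), with a median log2 fold change of -0.13 (camera adjusted p = 0.0224, and adjusted p = 0.85 with an estimated correlation). This set was no longer past the threshold without WT replicate 1 (camera adjusted p = 0.691) or RSK2KO replicate 2 (0.524). The calls were 9 lower without WT replicate 2, 1 lower without RSK2KO replicate 1, 1 higher and 1 lower without WT replicate 1 and 1 higher without RSK2KO replicate 2, and 8 genes passed in DESeq2. The 4 genes, RPL14, RPL29, RPSA and RPL32, all lie on chromosome 3, the first 3 inside its lowered segment. RPL14 was 1.37-fold lower (edgeR adjusted p = 0.014, and 0.056 without RSK2KO replicate 2). RPL29, RPSA and RPL32 each lost the call without WT replicate 1, RSK2KO replicate 1 or RSK2KO replicate 2 (edgeR adjusted p from 0.0509 to 0.152).

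Glycolysis and hypoxia genes were lower as a set, with 8 of 31 lower and none higher, also when adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 0.00748, and adjusted p = 0.806 with an estimated correlation). The list was not past the threshold without WT replicate 2 (camera adjusted p = 0.214), where 1 member was higher and 9 lower. PFKP, the platelet form of phosphofructokinase in a lowered segment of chromosome 10, was 1.86-fold lower, from 962 ± 44.8 to 517 ± 38.8 CPM (SD, n = 2 each, edgeR adjusted p = 0.00189). VEGFA, an angiogenic growth factor on this list and on the stress-response list, was 1.72-fold lower (edgeR adjusted p = 0.00329). Of 29 genes of the unfolded protein and integrated stress responses, 7 fell and 2 rose (9 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.055), but passed without the genes of the shifted chromosome segments (0.0226), and 1 member rose without RSK2KO replicate 2. ASNS, which makes asparagine, was 2.21-fold lower (edgeR adjusted p = 0.00459), and SLC7A11, the cystine transporter, was 1.88-fold lower (edgeR adjusted p = 0.00657). Cholesterol synthesis genes had 1 of 24 higher and none lower over all genes, and none either way when adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 2 past the threshold by DESeq2 (camera adjusted p = 0.663). That list depended on the WT libraries: without WT replicate 2, 11 members were higher (camera adjusted p = 3.55e-06), and without WT replicate 1, 2 were higher and 7 lower (camera adjusted p = 0.052, direction turned). It also turned without RSK2KO replicate 2 (camera adjusted p = 0.798), with 1 lower.

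Adhesion, matrix and motility genes were lower as a set. Of 37 tested, 13 fell and 3 rose, 14 fell and 5 rose when adjusted over the list alone, and the median log2 fold change was -0.35 (camera adjusted p = 0.00616, and adjusted p = 0.806 with an estimated correlation). The list was not past the threshold without RSK2KO replicate 2 (camera adjusted p = 0.118). The number higher was 5 without that library or WT replicate 1, and 1 without RSK2KO replicate 1. ITGAV, the integrin alpha V chain, was 1.71-fold lower, from 687 ± 28.1 to 401 ± 14.4 CPM (SD, n = 2 each, edgeR adjusted p = 0.00211). SERPINE1 and PLAU, the plasminogen activator inhibitor and urokinase, were 3.41-fold and 3.13-fold lower (edgeR adjusted p = 0.0028 and 0.003). CYR61, a matricellular protein, was 2.08-fold lower (edgeR adjusted p = 0.00293).

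Among 24 apoptosis regulators of the BCL2 and IAP families, 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.327), with 0 higher and 2 lower without RSK2KO replicate 1 or RSK2KO replicate 2. BCL2 was 18.3-fold lower, from 3.67 ± 2.49 to 0.194 ± 0.0462 CPM (SD, n = 2 each, edgeR adjusted p = 0.00702), although it lies in the raised segment of chromosome 18. Its log2 fold change moved from -4.19 to -3.26 without WT replicate 2. Of 26 targets of p53, 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.663), and GADD45A was 1.95-fold lower (edgeR adjusted p = 0.00627). The p53 list turned its direction without RSK2KO replicate 1 (camera adjusted p = 0.998), with 2 higher and 1 lower there, and 0 higher and 1 lower without RSK2KO replicate 2. Of 30 interferon-stimulated genes, 3 rose and 1 fell, also when adjusted over the list alone. That list had a median log2 fold change of 0.14 and a mean of -0.04, and its test pointed up (camera adjusted p = 0.497), with 8 higher and 2 lower without WT replicate 2. IFIH1, an RNA sensor, rose 3.28-fold (edgeR adjusted p = 0.00373), and GBP2 was 2.47-fold lower (edgeR adjusted p = 0.00482).

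Cell cycle genes gave few calls. In the list of G1/S and DNA replication, 1 of 36 genes passed, also when adjusted over the list alone. It was PCNA, the polymerase clamp, 1.51-fold higher (edgeR adjusted p = 0.0108, and 0.0519 without RSK2KO replicate 2) and inside a raised segment of chromosome 20. The list had a camera adjusted p of 0.601. It passed in the higher direction without RSK2KO replicate 1 (0.0105) and turned without RSK2KO replicate 2 (0.17). Its calls were 2 higher in the first case, 1 lower in the second, 1 higher and 1 lower without WT replicate 1, and 2 higher and 1 lower without WT replicate 2. None of 36 G2/M and mitosis genes passed in edgeR, over all genes or over the list alone, with 1 at an unadjusted p under 0.05 and 0 past the threshold by DESeq2 or limma-voom (camera adjusted p = 0.327). MKI67, a proliferation marker, stood at 264 ± 62.0 CPM in WT and 239.5 ± 72.3 CPM in RSK2KO (SD, n = 2 each, edgeR adjusted p = 0.706). The G2/M result rested on the choice of libraries: without WT replicate 2, 16 members were higher (camera adjusted p = 1.5e-06). The list also passed in the higher direction without RSK2KO replicate 1 (camera adjusted p = 0.0145), and without WT replicate 1 or RSK2KO replicate 2 the direction of the list turned (camera adjusted p = 0.108 and 0.934). None of 10 replication-dependent histone genes passed in edgeR, over all genes or over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (camera adjusted p = 0.663), and 1 was lower without RSK2KO replicate 2.

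Markers of other cell types were mostly below the expression filter. Of the fibroblast and stromal markers, 6 were tested, 1 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.327), with a median log2 fold change of -0.28, a mean of 0.07 and a test pointing down. Without WT replicate 2, 2 were higher and 2 lower, and without RSK2KO replicate 1, 1 was higher and 2 lower. COL3A1, a fibrillar collagen, was 6.72-fold higher at 9.21 ± 6.48 CPM (SD, n = 2, edgeR adjusted p = 0.0153), with a log2 fold change of 2.75 that moved to 1.74 without RSK2KO replicate 2, and TAGLN, an actin-binding protein, was 2.67-fold lower (edgeR adjusted p = 0.000731). Of 5 immune and endothelial markers tested, only VWF passed in edgeR, also over the list alone. It was 2.63-fold higher at 2.12 ± 0.27 CPM (edgeR adjusted p = 0.024), and its call was lost without WT replicate 1 (0.0616), RSK2KO replicate 1 (0.0563) or RSK2KO replicate 2 (0.111). That list had a camera adjusted p of 0.454, and it turned its direction without WT replicate 2 (0.895, with 1 higher and 1 lower) or RSK2KO replicate 1 (0.916).

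Mitochondrially encoded genes were higher as a set, with 2 of 13 higher and none lower (5 and none adjusted over the list alone) and a median log2 fold change of 0.44 (camera adjusted p = 0.0163, and adjusted p = 0.806 with an estimated correlation). They took 1.63% and 1.49% of the counts in the WT libraries, 2.42% in RSK2KO replicate 1 and 1.82% in RSK2KO replicate 2. The list was not past the threshold without RSK2KO replicate 1 (camera adjusted p = 0.167) or WT replicate 2 (0.0677). The number higher was 8 without RSK2KO replicate 2, 5 without WT replicate 1, 1 without WT replicate 2 and 0 without RSK2KO replicate 1. MT-ND6 rose 1.90-fold (edgeR adjusted p = 0.0441), and its log2 fold change of 0.92 moved to 0.47 without RSK2KO replicate 1, where the call was lost. Its call was also lost in DESeq2 (adjusted p = 0.126), whereas 6 of the 13 members passed in DESeq2, against 2 in edgeR.

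**Figure D2:**
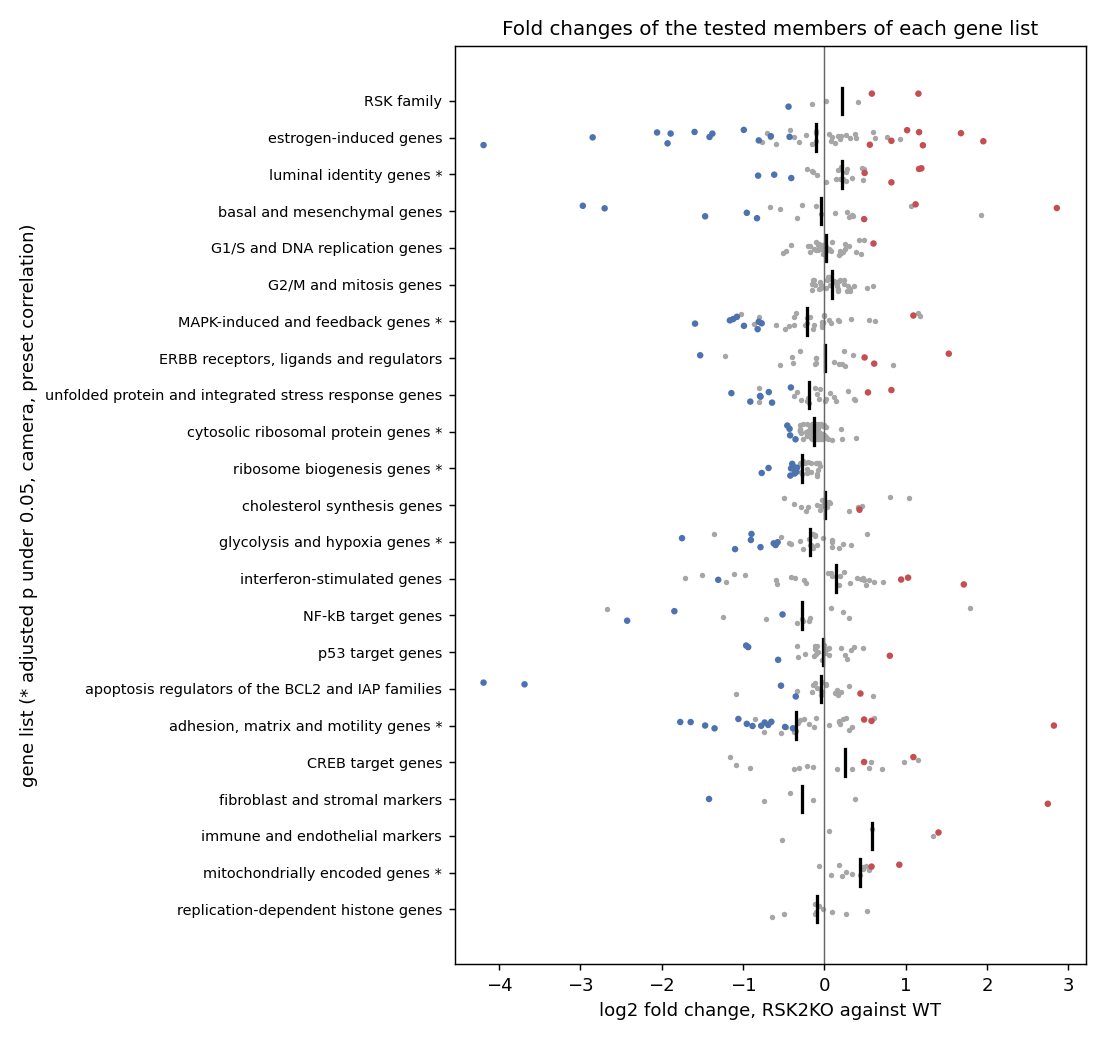
Each point is the log2 fold change (RSK2KO against WT) of 1 tested member of a gene list, red or blue where it was higher or lower at an adjusted p under 0.05 and grey otherwise, with a black bar at the median of the list and vertical offsets that only separate points. An asterisk marks the 7 lists past the threshold by camera with a preset correlation, of which ribosome biogenesis has all 30 members below 0.

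Fold changes were not spread evenly along the chromosomes. Running medians over 51 neighbouring genes reached 0.55, against at most 0.34 in 1000 random gene orders. Genes were lower as a whole in 4 segments, on chromosome 3 (28.3 to 94.0 Mb, 262 genes), chromosome 10 (0.1 to 45.4 Mb, 131 genes), chromosome 13 (51.9 to 114.3 Mb, 96 genes) and chromosome 15 (51.7 to 64.2 Mb, 59 genes). They were higher in 2 segments, on chromosome 18 (23.1 to 80.2 Mb, 123 genes) and chromosome 20 (0.3 to 18 Mb, 78 genes). Those of chromosomes 15 and 20 did not pass the limit of random orders without WT replicate 2, where their medians less that of all genes were 0.25 and 0.34 in their direction, against 0.36 and 0.37 with all libraries. That of chromosome 15 did not pass without WT replicate 1 either, at 0.39, and without RSK2KO replicate 1 a further segment passed on chromosome 17. The 6 segments held 5.7% of the genes placed and 303 of the calls, and 40.5% of their genes were called against 15.8% elsewhere. They were found from these same fold changes, so a higher share of calls inside them follows from the selection. With the genes of these segments left out, 932 genes were higher and 1026 lower.

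**Figure D3:**
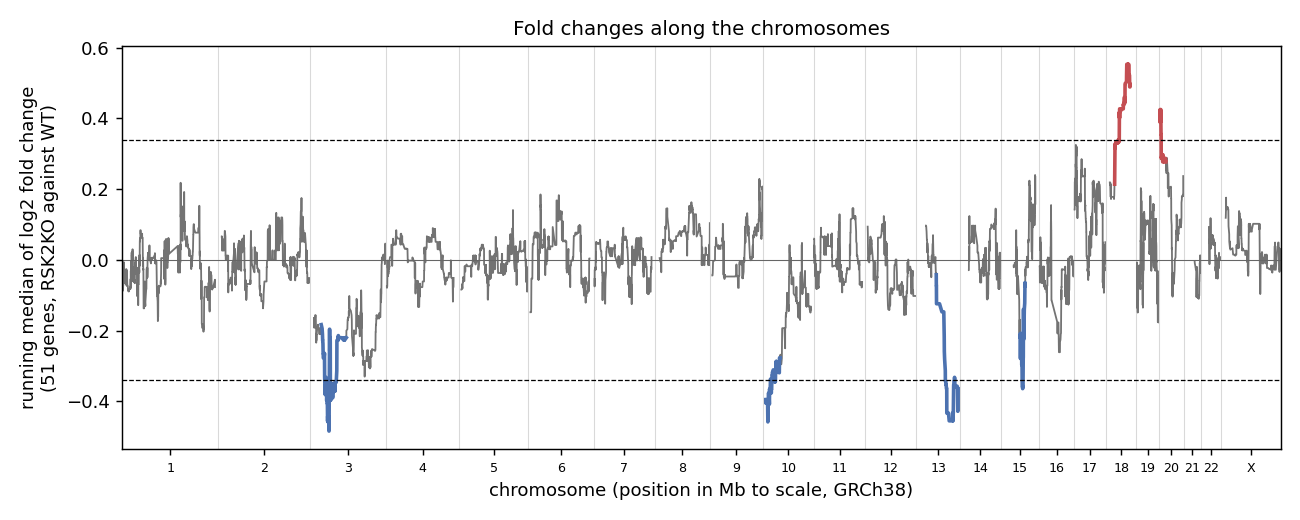
The line is the running median of log2 fold change (RSK2KO against WT, less the median of all genes) over 51 neighbouring genes along each chromosome in GRCh38, with the segments shifted as a whole in blue (lower) or red (higher) and dashed lines at 0.34 above and below 0, the largest value in 1000 random gene orders. The highest stretch is on chromosome 18, at 0.55.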

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

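The test of genes by RPKM, the search for shifted chromosome segments and the tests of segment medians with 1 library left out were chosen after the data were examined, whereas what the other tests of an explanation would show was set before their results were seen.

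A difference between the groups appeared in values that no comparison above uses. Among 400 genes whose counts are listed at 0 but whose RPKM could be tested, 4 were higher in RSK2KO than in WT and 9 were lower (limma, adjusted p under 0.05), with 57 at an unadjusted p under 0.05. The higher ones were RP3-523K23.2, a long noncoding RNA at 14.9 ± 2.01 against 5.97 ± 0.633 RPKM (SD, n = 2 each, limma adjusted p = 0.00308), its neighbour on chromosome 6 RP11-524H19.2, and the processed pseudogenes RP11-557C9.3, listed at 0 in both WT libraries, and RPL10P13. These genes were chosen after their values were seen, and pseudogene values are uncertain because reads can be shared with the parent gene.

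Neighbouring genes shifted together along 6 chromosome segments, which cover 749 genes. Small clusters of strongly changed genes are argued against as the only source. Without the genes called at 2-fold or more, the largest running median was 0.50, against 0.33 in random orders. That is 1 value over all chromosomes, so it does not speak for each segment. A departure of 1 library is argued against for the segments of chromosomes 3, 10, 13 and 18. These chromosomes passed the limit of random orders with each library left out in turn. The largest running median of all stayed at 0.47 or above, against 0.41, but it lay on chromosome 18 or 3 and does not speak for the others. The medians of the segments of chromosomes 3, 10, 13, 18 and 20 in their direction stayed at 0.32 or above, within bounds found with all libraries. For chromosome 20 only this median speaks against a departure, since its segment did not pass that limit without WT replicate 2. A departure of 1 library stays open for the segment of chromosome 15, whose median in its direction was 0.25 without WT replicate 2 (95% interval 0.12 to 0.43, against a bound of 0.18). A copy number difference between the cells of the groups may account for the segments and stays open. The 20 segment genes with RPKM only, not used to find the segments, had a median of 0.27 in the direction of their segment (95% interval -0.01 to 0.41). The median log2 difference was -0.01 for 9 of them on chromosome 3 and -0.03 for 3 on chromosome 13. It was -0.31 for 5 on chromosome 10 (95% interval -0.45 to -0.06), 0.26 for 2 on chromosome 18 and 0.30 for 1 on chromosome 20. A shift would also follow from an effect of the genotype on these regions. What was set beforehand asked only for a median of the 20 genes in the direction of their segment, which 0.27 meets. The demand that its interval exclude 0 was added when the test was scored and leaves the test undecided.

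RPS6KA3 fell by less than 2-fold in cells labelled as its knockout. A lower copy number of its region is argued against, since the 50 tested genes nearest to it (12.8 to 25 Mb of chromosome X) had a median log2 fold change of 0.16 (95% interval 0.06 to 0.29), above the bound of -0.22 set from the value of RPS6KA3. Scaling of the libraries is argued against as well, since the weakest of 3 scalings still gave -0.41 with an SE of 0.098. An edit that disrupts the protein and leaves part of the transcript is an open explanation that was not tested, as is a remainder of unedited cells, because the table gives no values per exon or allele.

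Mitochondrially encoded transcripts were higher in RSK2KO, with a median log2 fold change of 0.44. The result is consistent with a departure of RSK2KO replicate 1, since the median was 0.17 without that library. The medians were 0.69 without RSK2KO replicate 2, 0.46 without WT replicate 1 and 0.37 without WT replicate 2. An effect of the genotype on these transcripts stays open and was not tested apart from this.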

How the results depend on the processing

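Leaving out the genes of shifted segments and the authors' deposited comparison were chosen after seeing the data. So were searches for segments with 1 library left out or with other windows, and the other alternatives were chosen before. The counts of genes higher and lower stayed within 1.5 times of 1029 and 1232 under both other scalings, no filter, DESeq2, limma-voom, the removal of segment genes and the authors' deposited table. They moved to 191 and 195 with glmTreat and to 301 and 362 at an adjusted p under 0.01, as stricter criteria, and ranged from 503 to 1219 higher and 576 to 1346 lower with 1 library left out. RPS6KA3 ranged from -0.54 to -0.32 with 1 library left out. Its log2 fold change of -0.44 was not past the threshold with glmTreat (adjusted p = 1) or at 0.01. Of 7 lists past the threshold, 0 passed with an estimated correlation, with 0 at an unadjusted p under 0.05, and 0 passed with fry's test of a change in 1 direction. The estimated correlation was 0.90 for ribosomal protein, 0.86 for mitochondrially encoded, 0.33 for adhesion, 0.29 for glycolysis and hypoxia and 0.28 for ribosome biogenesis genes. It was 0.0103 for MAPK and -0.0076 for luminal genes, near or below the preset 0.01, so a higher correlation does not account for their loss. With 2 libraries per group, camera with an estimated correlation has few residual degrees of freedom and little power. Its result therefore cannot tell a list that did not shift from a shifted list that it could not detect. Over all 23 lists, fry's test of a change in 1 direction gave 0 past the threshold and 6 at an unadjusted p under 0.05. Those 6 included the luminal, MAPK and ribosome biogenesis lists but not the other lists past the threshold. Fry's mixed test, of change in either direction without comparison with other genes, passed for 17 of the 23 lists and 5 of the 7. The number of lists ranged from 6 to 9, and that of chromosomes with a shifted segment from 4 to 7, with 1 library left out. Of the calls, 1885 were also past the threshold in the authors' deposited table, all in the same direction. The estrogen-induced list ranged from an adjusted p of 0.000269 to 0.797 with 1 library left out, and its direction turned at 0.797, without WT replicate 2; the cause was not tested.

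Samples with the same replicate number deviated from their group means with a correlation of 0.08 across the tested genes. This cannot decide whether the numbers pair the samples. A shift shared by some genes need not show in it, and the medians of some lists below followed the number. With the replicate number as a block, 1464 genes were higher and 1626 lower, and the estrogen-induced list passed at an adjusted p of 0.0401.

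Directions turned for results that did not pass the threshold, and the cause was not tested. For G2/M genes the median log2 fold change was 0.10 with all libraries. It was 0.39 without WT replicate 2 and 0.24 without RSK2KO replicate 1, but -0.16 without WT replicate 1 and -0.025 without RSK2KO replicate 2. The medians of cholesterol synthesis and G1/S genes moved up and down in the same cases. A lower level in replicate 1 than in replicate 2 of both groups would give this order. The immune and endothelial list turned without a filter (adjusted p = 0.748). With 1 library left out, lists turned in at least 1 case. Their adjusted p ranged from 0.794 to 0.916 for that list, 1.5e-06 to 0.934 for G2/M, 3.55e-06 to 0.798 for cholesterol synthesis, 0.566 to 0.998 for p53, 0.00985 to 0.566 for basal and mesenchymal and 0.0105 to 0.973 for G1/S genes. The log2 fold change ranged from -0.48 to 0.15 for MKI67 and from -0.21 to 0.01 for HIST2H2BE. Of 86 named genes past the threshold besides RPS6KA3, 61 kept the call with each library left out and 25 lost it at least once. The simulated recovery of 44% at 1.5-fold, with 2 libraries per group, was for 200 changed genes among 13121. It sets no limit for these data, where 17.2% of genes were called, because recovery at an adjusted p depends on the share of genes changed.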

Other observations

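The tests in this part were chosen after the data were examined.

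Noncoding transcripts that the count tests leave out also differed between the genotypes. TGFB2-AS1, a noncoding RNA antisense to TGFB2, was lower in RSK2KO at 1.95 ± 0.0636 RPKM against 6.09 ± 0.61 RPKM in WT (SD, n = 2 each, log2 fold change -1.59 on the log2(RPKM + 0.1) scale, limma adjusted p = 0.00172). TGFB2 itself, a ligand of the TGF-beta family, was lower in the counts (log2 fold change -1.82, edgeR adjusted p = 0.000267). These genes were chosen after their values were seen. Because the use of strand is not given, reads from this pair cannot be told apart by gene. The neighbouring mitochondrial pseudogenes MTND3P22 and MTCO3P39 on chromosome 4 had log2 fold changes of -3.08 and -2.23 (limma adjusted p = 0.00172 and 0.0026), opposite in sign to the median of the mitochondrially encoded genes.

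Across 406 tests of genes that share a symbol root, 1 passed. Genes of the DOCK family, guanine nucleotide exchange factors for RAC and CDC42, were lower in 6 of 10 tested (Fisher's exact test, one-sided, adjusted p = 0.0414). They were DOCK1, DOCK5, DOCK6, DOCK8, DOCK9 and DOCK10, and 1 other member, DOCK11, was higher. DOCK9 lies in the lowered segment of chromosome 13, and whether the family passes without it was not tested.

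The 7 cytosolic ribosomal protein genes on chromosome 3 had a median log2 fold change of -0.35, and the 69 on other chromosomes one of -0.12.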
